A study of Rattus norvegicus with 12 samples.

How the data were processed

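RNA was sequenced from laser-microdissected deep and superficial CA1 sublayers of 3 control and 3 epileptic rats, 12 libraries in all. Per the labels' protocols, brains were frozen, the hippocampus was cut in 20 µm sections, and cell bodies of each sublayer were collected separately before total RNA was extracted. The same protocols name no marker gene for choosing the regions. The values are raw gene counts, whole numbers of reads per gene without normalization, as deposited by the authors in 1 table per library. The submitters' processing notes name FastQC 0.11.3, STAR 2.5.0c, SAMtools 0.1.19 and HTSeq 0.6.1 and the genome build Rnor_6.0, with no settings; whether reads were counted by strand is not given in the sources used here, so reads of a gene and an overlapping or antisense partner may not be told apart, nor those of near-identical copies.

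Each table listed 32662 Ensembl gene identifiers and 5 summary tallies. The tallies were left out of library sizes and tests. Of all alignments tallied, 28.6 to 35.1% were assigned to a gene and 22.3 to 44.0% to no feature, termed outside annotated exons below. As strand use is not given, alignments on the opposite strand of an exon may be among the latter. A further 25.2 to 45.6% were not unique and 0.207 to 0.300% were ambiguous. The tallies for low quality and for not aligned were 0 in all libraries. None of the identifiers could be paired with a symbol, 0 of 32662, because the gene table at hand carries no Ensembl identifiers and follows another assembly. The main tests, designs, filters and 33 gene lists were fixed before the data were examined. The lists with their set tests and the alternative without mitochondrially encoded genes were therefore not analysed here. Gene positions, GC content and gene length were not used here.

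Libraries were grouped by the sublayer and condition in their labels, and the replicate number was taken as the animal. Deviations of the deep and superficial libraries of 1 number from their group means correlated across identifiers in all 6 pairs (r = 0.466 to 0.829), and both sublayers were cut from the same brains per the labels' protocols. Sublayers were therefore compared within animals. Control and epileptic libraries of 1 number come from different animals. Their deviations correlated at 0.281, 0.204 and 0.397 in deep and 0.283, −0.0429 and 0.220 in superficial libraries for numbers 1, 2 and 3, so that a fit with the number as a block is given beside the deep result and, for the superficial result, only with the alternatives. No 2 libraries of a group were duplicates, as the chi-square per identifier between replicates was 7.07 to 122.

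Counts were analysed in R 4.3.3 with edgeR 4.0.16. Identifiers were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersions was applied, with Benjamini-Hochberg adjustment and a threshold of 0.05. The sublayer difference in controls, in epileptic rats, and the difference between these were tested in 1 model of all 12 libraries with a term for each animal. Epilepsy was tested separately in the 6 deep and the 6 superficial libraries, 3 animals against 3. Fold changes are superficial relative to deep, or epileptic relative to control. The SE printed with an edgeR fold change is its absolute log2 value divided by the square root of the test's F statistic. It is an approximation and was not taken from the fit itself. Library-size-scaled counts (CPM, log2 CPM) used TMM-scaled library sizes, which were 16135358 to 25893962 gene counts before filtering and scaling, and principal components used log2 CPM with a prior count of 2. The p-values of the epilepsy tests measure the spread between animals, which are 3 per condition. Those of the sublayer tests measure the spread of the within-animal difference, once the level of each animal is taken out. That spread is estimated from all 6 animals together. The sets of identifiers called in controls were tested in epileptic rats with fry of limma 3.58.1. Per-animal measures were compared by exact permutation of the 3 against 3 animals or exact sign flips over 6 animals.

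The rule for named identifiers required an adjusted p below 0.05, a mean log2 CPM of at least 3 and the same direction in all animals, and took the largest changes in each direction. Where fewer than 5 identifiers passed, those of smallest p were named as not passing. The rule also required a gene symbol, a condition that could not be applied, and at most 2 identifiers in each direction are named per comparison.

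Before use, the tests were checked on simulated counts with the real means and library sizes and 67 identifiers changed by each of 3 folds. In the sublayer model, 98.5% of the 1.5-fold and 100% of the 2-fold changes were recovered, 5.66% of the calls were false, and 0 calls were made where none had been planted. With the spread seen in the 6 deep libraries, 50.8% of the 1.5-fold and 94.0% of the 2-fold changes were recovered, with 6.29% false calls. With that of the 6 superficial libraries, recovery was 40.3% and 83.6%, with 13.4% false calls, above the nominal 5%. The limit set for that share in the check had been lower and was raised after this value was seen.

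Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with sample quality weights, limma-voom with the animal as a random effect, no low-count filter, a filter of at least 1 CPM in every library of a group, other designs (with or without a block, other libraries in the fit), and leaving out each animal or library. Alternatives added after seeing the data left out the 2 most abundant identifiers or took the share outside annotated exons as a covariate.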

Results

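Gene expression was measured by RNA sequencing in the pyramidal cell layer of hippocampal area CA1 of adult male Wistar rats. The deep sublayer, on the side of the stratum oriens, and the superficial sublayer, on the side of the stratum radiatum, were collected separately by laser microdissection. Epileptic rats had received repeated doses of 5 mg/kg kainate, an agonist of ionotropic glutamate receptors, until they entered status epilepticus, and were sampled 6 to 8 weeks later in the chronic phase. Control rats had received vehicle. Both sublayers were taken from each of 3 control and 3 epileptic rats, which gave 12 libraries in 4 groups of 3. The design asks how deep and superficial CA1 cells differ, whether that difference is altered in chronic epilepsy, and what epilepsy changes within each sublayer. Genes are given by their Ensembl identifiers, because the files do not pair these with gene names, and no function is assigned to them. Deep and superficial cells below stand for the tissue collected from each sublayer. The fixed lists of cell type genes were not run. A difference in the cell make-up of the collected tissue therefore cannot be told apart from a difference within cells, for the sublayer and the epilepsy comparisons alike.

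The libraries held 16135358 to 25893962 counts assigned to genes, with at most 19550582 in the 6 control libraries and at least 20623196 in the 6 epileptic libraries. Between 18523 and 19558 identifiers had at least 1 count in a library. A single identifier, ENSRNOG00000043866, held 11.99% ± 0.886 of the gene counts in deep control libraries and 8.65% ± 0.622 in superficial control libraries (SD, n = 3 each). The same identifier held 20.7% ± 3.51 in deep and 16.2% ± 4.55 in superficial epileptic libraries (SD, n = 3 each). Its share was lower in the superficial than in the deep library in 6 of 6 animals (superficial minus deep −3.87 ± 1.17 percentage points, SD, n = 6; exact sign-flip permutation test, two-sided, p = 0.03125, adjusted p = 0.09375 over 3 library measures). The mean over both sublayers was 18.5% ± 4.02 in epileptic and 10.3% ± 0.500 in control animals (SD, n = 3 each), with p = 0.1 in an exact permutation test, the smallest two-sided value that 3 animals against 3 can give, and an adjusted p of 0.3. ENSRNOG00000030478 was the second most abundant identifier, with 2.33 to 5.94% of the gene counts.

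The largest axis of variation lay between the epileptic animals rather than between the sublayers. The first principal component carried 50.6% of the variance and placed the 6 control libraries between −36.6 and −11.9. Deep and superficial libraries of epileptic animal 1 fell at −12.7 and −15.7, within that range, but lay at −30.4 and −30.7 on the second component (14.0% of the variance), where the control libraries lay at 6.82 to 17.1. On the first component the libraries of animal 2 lay at 22.0 and 28.4 and those of animal 3 at 55.1 and 71.4. The sublayers separated on the third component, with 8.79% of the variance, on which the superficial library lay below the deep one in each of the 6 animals. The typical distance between libraries, the median absolute log2 ratio over 9493 identifiers, was 0.09 to 0.15 between control animals of 1 sublayer. The mean distance of an epileptic library from the controls of its sublayer was 0.15, 0.16 and 0.21 in deep and 0.14, 0.18 and 0.24 in superficial CA1 for animals 1, 2 and 3. The biological coefficient of variation between animals was 17.1% in deep and 19.04% in superficial epileptic libraries, against 8.43% and 8.13% in the control libraries.

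**Figure D1:**
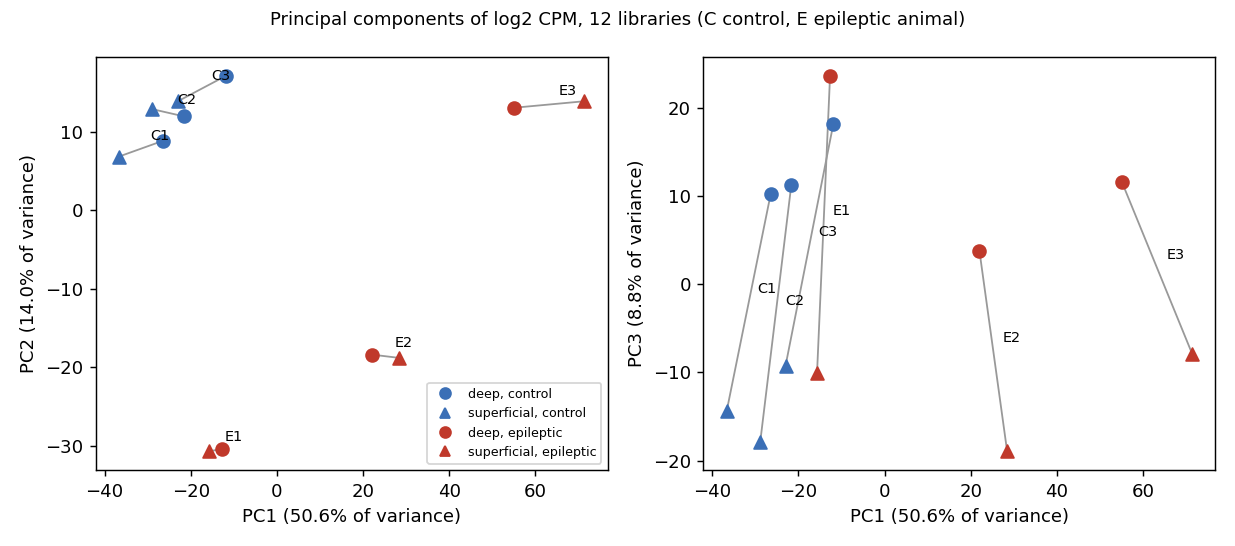
Principal components of log2 library-size-scaled counts (CPM) for the 12 libraries, with the first component (50.6% of variance) on the horizontal axes and the second (14.0%) and the third (8.79%) on the vertical axes. Each point is 1 library, circles are deep and triangles superficial, blue is control and red epileptic, and lines join the libraries of 1 animal. Control libraries lie between −36.6 and −11.9 on the first component and epileptic animal 3 lies at 55.1 and 71.4.

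In control rats, deep and superficial CA1 differed in the expression of 1248 of 14791 identifiers tested (8.44%), 630 of them higher in superficial and 618 higher in deep cells. All 1248 differed in the same direction in each of the 3 control animals, for which a test within animals selects, so this adds no evidence of its own. The differences were mostly small: the median absolute log2 fold change of the called identifiers was 0.37, and at least 2-fold differences numbered 23 in the superficial and 51 in the deep direction. ENSRNOG00000021067 was higher in superficial cells, with a library-size-scaled count (CPM) of 21.3 ± 1.75 against 9.68 ± 0.942 in deep cells (SD, n = 3; log2 fold change 1.14, SE 0.11, adjusted p = 1.232e-05). ENSRNOG00000025115 was also higher in superficial cells, with 15.5 ± 3.27 against 7.20 ± 1.42 CPM (SD, n = 3; log2 fold change 1.11, SE 0.11, adjusted p = 2.323e-05). In the other direction, ENSRNOG00000006200 was higher in deep cells, at 15.4 ± 5.72 against 3.69 ± 1.51 CPM (SD, n = 3; log2 fold change −2.06, SE 0.15, adjusted p = 9.465e-07). ENSRNOG00000004554 had 34.1 ± 3.09 CPM in deep and 11.7 ± 1.60 in superficial cells (SD, n = 3; log2 fold change −1.55, SE 0.14, adjusted p = 6.182e-05). The test was edgeR's quasi-likelihood test with each animal as a block, and 3376 identifiers (22.8%) lay at an unadjusted p below 0.05. The count fell to 424, 416 and 420 without control animal 1, 2 or 3, and rose to 1977 and 2071 without epileptic animal 1 or 3, whose libraries enter the shared estimate of the spread. DESeq2 called 820 identifiers, limma-voom with sample quality weights 2523 and with the animal as a random effect 689, while edgeR called 2375 from the 6 control libraries alone, 1910 with no low-count filter and 5 without the animal as a block.

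In epileptic rats, 1484 identifiers differed between the sublayers, 745 higher in superficial and 739 higher in deep cells, and 1424 of them (96.0%) had the same direction in all 3 animals. That share was 42.0% over all identifiers tested, and the test selects for a common direction, so the 96.0% adds no evidence of its own. The median absolute log2 fold change was 0.34, with 61 superficial and 41 deep differences of at least 2-fold. ENSRNOG00000012094 was higher in superficial epileptic cells, at 21.5 ± 6.91 against 8.23 ± 2.97 CPM in deep cells (SD, n = 3; log2 fold change 1.40, SE 0.09, adjusted p = 4.171e-07). ENSRNOG00000032708 was higher in superficial cells with a log2 fold change of 1.20 (SE 0.11, adjusted p = 2.613e-05), but its level differed widely between epileptic animals, at 28.2 ± 35.9 CPM in superficial and 11.9 ± 14.6 CPM in deep libraries (SD, n = 3), and it had 0.0537 and 0.117 CPM in the control sublayers. Its call was lost in limma-voom with the animal as a random effect (log2 fold change 1.01, adjusted p = 0.5305; range over the alternatives 1.33e-21 to 0.8797). ENSRNOG00000006200 was again higher in deep cells (log2 fold change −1.90, SE 0.13, adjusted p = 5.923e-07), as was ENSRNOG00000030877, with 18.6 ± 3.63 CPM in deep and 5.05 ± 1.21 in superficial epileptic libraries (SD, n = 3; log2 fold change −1.88, SE 0.13, adjusted p = 8.445e-07). At an unadjusted p below 0.05 there were 3825 identifiers. The count fell to 536 without epileptic animal 2, and DESeq2 called 820, limma-voom with sample quality weights 2585 and with the animal as a random effect 838, a fit of the 6 epileptic libraries alone 727, and edgeR without the animal as a block 5. The biological coefficient of variation within animals was 4.12% in control and 6.92% in epileptic rats, while the main fit shares 1 spread. Fitted alone, controls gave 2375 calls against these 727, so the main counts do not rank the conditions.

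Most of the sublayer differences seen in control rats were present in epileptic rats. Of the 1248 identifiers called in controls, 95.4% had the same direction in epileptic animals, 615 of the 630 superficial-higher and 576 of the 618 deep-higher ones, compared with 70.1% of all identifiers tested. In total 690 were called in both conditions with the same direction, 341 higher in superficial and 349 higher in deep cells, where independent lists of these sizes would share 31.7 and 30.9, and 1 was called in opposite directions. The median log2 fold change of the superficial-higher identifiers was 0.31 in control and 0.24 in epileptic rats, and that of the deep-higher identifiers −0.45 and −0.32. A smaller median in the second condition follows in part from choosing the identifiers in the first. Both sets moved on balance in their control direction in epileptic animals by limma's fry rotation test (superficial-higher adjusted p = 0.002608, deep-higher adjusted p = 0.0005023). Across identifiers, which are not independent replicates, the log2 fold changes of the 2 conditions had a Pearson r of 0.40 and a Spearman rho of 0.47.

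**Figure D2:**
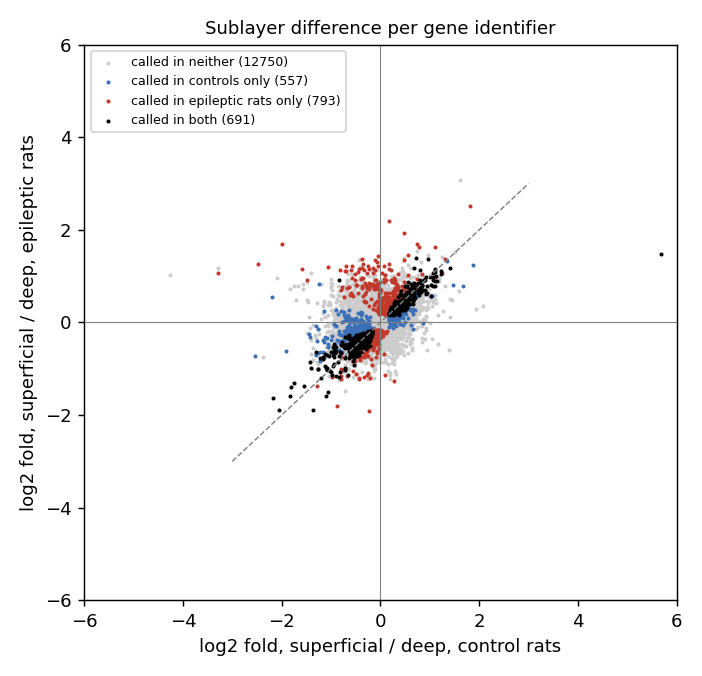
Log2 fold change between superficial and deep CA1 in control rats (horizontal axis) and in epileptic rats (vertical axis), with 1 point per gene identifier and positive values higher in superficial cells. Black points were called in both conditions, blue in controls only and red in epileptic rats only, grey in neither, and the dashed line marks equal values. Of the 1248 identifiers called in controls, 95.4% had the same direction in both conditions.

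The size of the sublayer difference within each animal was then compared on identifiers called in the animals of the other replicate numbers. The mean log2 difference, signed by the direction in those animals, was 0.32, 0.43 and 0.27 in control animals 1, 2 and 3 and 0.40, 0.36 and 0.15 in epileptic animals 1, 2 and 3. The lists held 1772, 876 and 3287 identifiers for numbers 1, 2 and 3, each shared by the control and the epileptic animal of that number, so the values are comparable within a number only. Epileptic minus control, the difference was 0.08, −0.07 and −0.12 within numbers 1, 2 and 3 (mean −0.04 ± 0.11, SD, n = 3; exact sign-flip permutation test, two-sided, p = 0.75, where 3 pairs cannot give less than 0.25). In epileptic animal 3, 71.3% of the identifiers had the direction seen in the animals used to choose them, against 91.8% in control animal 3, scored on the same list. The other numbers went slightly the other way, with 95.6% in epileptic against 93.5% in control animal 1. For number 2 the shares were 98.2% and 97.9%.

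For single identifiers, a direct test of whether the sublayer difference itself differed between epileptic and control rats called 0 of 14791 with edgeR's quasi-likelihood test, with 976 (6.60%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.1216. DESeq2 called 2, limma-voom with sample quality weights 107, limma-voom with the animal as a random effect 0, and edgeR with no low-count filter 178. Without epileptic animal 1 the edgeR count was 84, and without epileptic animal 3 it was 12. Where calls were made, most were relatively higher in superficial cells of epileptic rats, 91 of 107 with quality weights, 153 of 178 with no filter, 80 of 84 without animal 1 and 8 of 12 without animal 3. These fits share libraries and are not separate evidence. Over all identifiers tested the median difference in log2 fold change was −0.00589. TMM scaling holds that median near 0, so it cannot show whether such a lean is present. ENSRNOG00000013578 had the smallest p, with a difference of 1.76 between the 2 log2 fold changes (SE 0.27, adjusted p = 0.1216), followed by ENSRNOG00000005195 at 0.58 (SE 0.10, adjusted p = 0.131). In edgeR with no low-count filter their adjusted p fell to 1.486e-09 and 2.825e-11 at nearly the same differences, 1.755 and 0.5747. The 178 calls of that fit can therefore not be set beside those of the filtered fits. In the other direction, ENSRNOG00000002773 had −0.45 and ENSRNOG00000021745 −0.44 (SE 0.10 and adjusted p = 0.2953 for both), and none of these 4 passed the test as fitted here. The 557 identifiers called in controls only and the 793 called in epileptic rats only are therefore not shown to differ between the conditions.

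Between epileptic and control rats, 2 identifiers differed in superficial CA1 and none passed in deep CA1 in the fit without a block. In superficial libraries ENSRNOG00000018159 rose from 1.40 ± 0.187 CPM in control to 10.7 ± 3.42 CPM in epileptic rats (SD, n = 3; log2 fold change 2.95, SE 0.27, adjusted p = 0.0265). ENSRNOG00000054809 fell from 16.3 ± 0.724 to 1.84 ± 0.613 CPM (SD, n = 3; log2 fold change −3.12, SE 0.23, adjusted p = 0.009799). The call of ENSRNOG00000018159 was lost with the share of alignments outside exons as a covariate (log2 fold change 2.75, adjusted p = 0.08942) and without epileptic animal 2 (2.67, adjusted p = 0.06671), and both calls were lost without any 1 of the control libraries (adjusted p = 0.1882 to 0.3543). In deep libraries ENSRNOG00000054809 had 8.03 ± 0.520 CPM in control and 1.25 ± 0.606 CPM in epileptic rats (SD, n = 3), a log2 fold change of −2.67 (SE 0.33) that did not pass (adjusted p = 0.0519). The same adjusted p applied in deep CA1 to ENSRNOG00000014819 (log2 fold change 0.76, SE 0.09), ENSRNOG00000057556 (0.83, SE 0.10) and ENSRNOG00000045967 (−3.44, SE 0.38). With the replicate number as a block all 4 passed, at an adjusted p of 0.01506, 0.01736, 0.01766 and 0.01095 in the order given. The number pairs different animals of the 2 conditions, so these values do not settle the calls. Over the alternatives that kept all 6 deep libraries the adjusted p of these 4 ranged from 1.086e-10 to 0.056, and without 1 library from 0.003943 to 0.3269. In superficial CA1, ENSRNOG00000020679 at 3.03 (SE 0.34) and ENSRNOG00000016069 at −0.93 (SE 0.11) had an adjusted p of 0.05813. With edgeR's quasi-likelihood test on 3 against 3 animals, 1947 of 14261 identifiers (13.7%) in deep and 2710 of 14321 (18.9%) in superficial CA1 lay at an unadjusted p below 0.05. With the share of alignments outside exons as a covariate, chosen after seeing the data, these numbers were 1659 and 997. The groups did not overlap for 18.7% of the identifiers in deep and 24.2% in superficial CA1, where chance gives 10%.

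The number of identifiers called between epileptic and control rats depended on the test and on single animals. In deep CA1, DESeq2 called 376, limma-voom with sample quality weights 2171, limma-voom with the animal as a random effect 47, and edgeR with the replicate number as a block 239. The balance of directions changed with the fit as well: 165 of the 239 calls with the block and 250 of the 376 by DESeq2 were higher in epileptic rats, against 16 of the 47 with the random effect, 16 of the 48 in a fit of all 12 libraries, 3 of 8 with RLE size factors and 50 of 99 with the share outside exons as a covariate. In superficial CA1 DESeq2 called 885 (527 higher) and the 2 limma-voom fits 1789 (842 higher) and 291 (105 higher). Leaving out epileptic animal 1, which lay closest to the controls, gave 552 calls in deep and 1443 in superficial CA1, and leaving out epileptic animal 3 gave 275 and 409. Without epileptic animal 2 there was 1 call in each sublayer, and without any 1 of the control animals there were 0 in either, with 1050 to 1444 identifiers in deep and 1374 to 1896 in superficial CA1 at an unadjusted p below 0.05. Fitted changes of at least 2-fold among identifiers above a mean log2 CPM of 3 numbered 78 in deep CA1 (65 higher and 13 lower in epileptic rats, 0 called) and 206 in superficial CA1 (185 higher and 21 lower, 1 called). Their median biological coefficient of variation was 38.0% in deep and 44.5% in superficial CA1, against 11.6% and 12.02% for the other identifiers. A choice by the fitted change in the same libraries favours identifiers of large spread.

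The fitted epilepsy differences in deep and superficial CA1 were correlated, but the sublayers came from the same animals and are not independent of each other. Across 14085 identifiers, which are not independent replicates, the log2 fold changes in deep and superficial CA1 had a Pearson r of 0.87 and a Spearman rho of 0.80, and 81.2% had the same sign. At an unadjusted p below 0.05 in both sublayers there were 1269 identifiers with the same direction, where independent lists would share 184, and 0 with opposite directions. With the same 6 animals regrouped in the 9 other ways, r was 0.63 to 0.85, the share of the same sign 67.2 to 78.7% and the number in both sublayers 19 to 910, with 0 of opposite direction in any. Each of these groupings gave a high correlation as well, so the values do not separate an epilepsy effect common to both sublayers from the sharing of animals. The interquartile range of the log2 fold changes was 0.31 in deep and 0.37 in superficial CA1.

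The make-up of the libraries differed among the epileptic animals as well. Alignments assigned to no feature, termed outside annotated exons here, may include those on the opposite strand of an exon. They made up 35.8 to 44.0% of the tallied alignments in control libraries, and 43.0% and 37.7% in the deep and superficial libraries of epileptic animal 1. Their share was 26.7% and 25.3% in animal 2 and 22.3% and 25.6% in animal 3. Averaged per animal, it was 30.1% ± 8.93 in epileptic and 41.2% ± 2.69 in control rats (SD, n = 3 each; exact permutation test, two-sided, p = 0.2, adjusted p = 0.3 over 3 measures). Alignments that were not unique made up 37.4% ± 8.41 in epileptic and 29.2% ± 2.35 in control rats (SD, n = 3 each; exact permutation test, p = 0.3, adjusted p = 0.3). The 2 epileptic animals with the lowest share outside exons were those farthest from the controls on the first principal component.

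**Figure D3:**
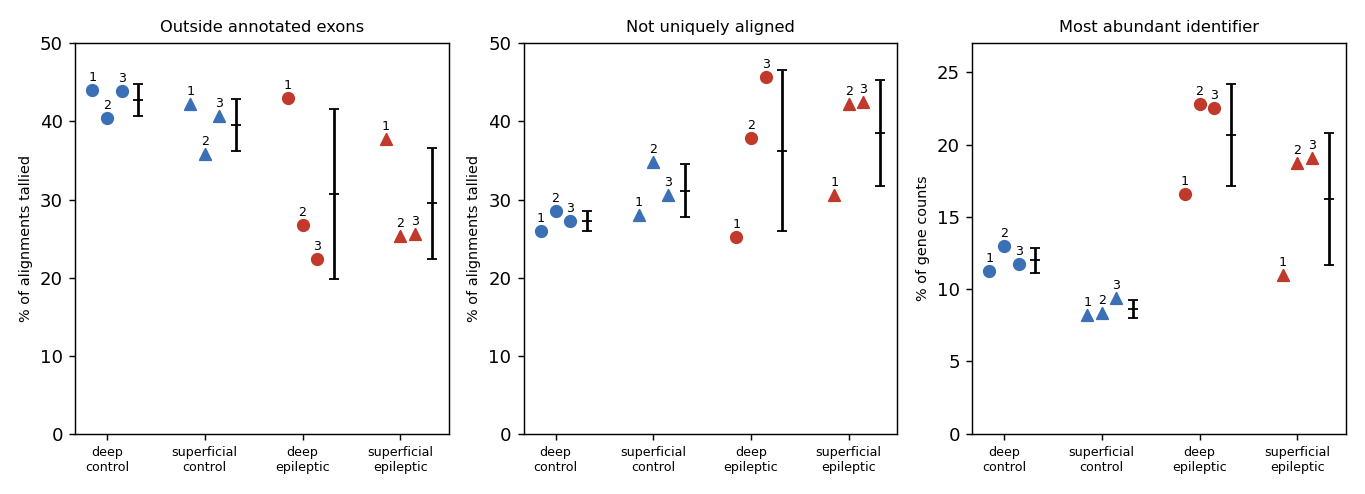
Percent of tallied alignments assigned to no feature (titled outside annotated exons), percent not uniquely aligned, and percent of gene counts held by the most abundant identifier, for each library in the 4 groups. Points are libraries numbered by animal, and the bar beside each group is the mean ± SD of its 3 libraries. The deep and superficial libraries of epileptic animals 2 and 3 lie between 22.3 and 26.7% outside exons, below the 35.8 to 44.0% of the control libraries.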

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

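The tests of the share of alignments outside exons, of opposite sublayer directions over all identifiers and of the spread between epileptic animals were chosen after those values had been seen. Groups of 3 libraries were too small for a test of single outlying libraries.

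Alignments that were not unique, which enter no comparison of gene counts, exceeded the highest control library (34.8%) in both libraries of epileptic animals 2 and 3. They made up 37.9% in the deep and 42.3% in the superficial library of animal 2, and 45.6% and 42.5% in those of animal 3. The libraries of epileptic animal 1 had 25.2% and 30.6%.

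The 2 identifiers with the smallest p for a change of the sublayer difference with epilepsy had opposite directions in the animals of the conditions, to which their choice by p contributes. Over all 14791 identifiers tested, 314 (2.12%) had one direction in all 3 control and the other in all 3 epileptic animals. Of these, 150 were relatively higher in superficial epileptic cells and 164 lower. Signs drawn at random would give 3.13%, but 70.1% of all identifiers shared their direction between the conditions. Directions common to both conditions lower the share, so it does not show whether changes with epilepsy are rare. ENSRNOG00000013578 was lower in superficial than in deep cells in 3 of 3 control and higher in 3 of 3 epileptic animals, a difference in log2 fold change of 1.76, and ENSRNOG00000005195 did the same with a difference of 0.58. The difference itself was tested with edgeR's quasi-likelihood test and did not pass (adjusted p = 0.1216 and 0.131). Both passed with DESeq2 (adjusted p = 0.003205 and 0.0002572), with limma-voom and sample quality weights (0.008246 and 0.008585), with no low-count filter, without epileptic animal 1 (0.003331 and 0.01609) and without epileptic animal 3 (0.03565 and 0.01823). Neither passed under the other alternatives, and over all of them the adjusted p ranged from 1.486e-09 to 0.9999 for the former and from 2.825e-11 to 0.9999 for the latter. The smallest values came from the fit with no low-count filter, where the differences themselves hardly changed.

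Epileptic animals 2 and 3 lay far from the controls. A difference in sequencing depth is argued against, since with all libraries thinned to equal gene totals the nearest of their 4 libraries still lay at a mean median absolute log2 ratio of 0.168196 from the controls, above the largest distance between control animals of 1 sublayer, 0.147. The deep library of epileptic animal 1 also lay above that bound, at 0.151, and its superficial library below, at 0.139, so the bound does not by itself set animals 2 and 3 apart. Leaving out the 2 most abundant identifiers could not decide whether a few identifiers taking most counts account for the distance. A median over many TMM-scaled identifiers hardly depends on 2 of them. The nearest of the 4 libraries lay at 0.165 as deposited and at 0.168712 after, against a bound of 0.150 after. The libraries of animal 1 then lay at 0.152 and 0.140. The lower share of alignments outside exons cannot be told apart from the animals, because 0 control libraries had a share as low as theirs. A different severity or course of the epilepsy in these animals may also account for the distance, and no value here tests it.

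Few identifiers passed between epileptic and control rats although many lay at a low unadjusted p. At the spread of control animals, the number of animals and reads sufficed for 2-fold changes. At least 98.51% of these were recovered when planted in simulated data of this size. That setting does not address power at the spread of the epileptic animals. The spread between epileptic animals was larger, with a biological coefficient of variation 2.02 times that of the controls in deep and 2.34 times in superficial CA1. With the spread seen, 94.0% and 83.6% of planted 2-fold changes were still recovered in deep and superficial CA1. That simulation gave epileptic and control libraries the same pooled spread and drew each identifier independently. It therefore cannot decide whether the larger spread of the epileptic animals accounts for missing changes of that size. The larger spread could account for missing smaller changes. Recovery of 1.5-fold changes was 50.8% and 40.3% with the spread seen, and 86.6% and 91.0% with that of controls. Identifiers with a fitted change of at least 2-fold were not of typical spread, to which their choice by the fitted change in the same libraries contributes. Their median biological coefficient of variation was 38.0% in deep and 44.5% in superficial CA1, against 11.6% and 12.02% for the others. The planted identifiers were picked without regard to spread, so power for such identifiers was not tested. What keeps the calls few stays open.

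Other groupings of the same libraries were too few for a share below 0.05, with a least possible share of 0.25 for sublayers and 0.1 for the other comparisons. The real sublayer labels gave 1248 calls in controls and 1484 in epileptic rats, the highest among the other swaps being 0 and 2, so that 1 of 4 swaps reached the real count in each case. For the difference between conditions of the sublayer effect, 5 of 10 groupings reached the 976 identifiers at an unadjusted p below 0.05 (highest other 1422), with 0 calls for the real grouping and 6 at most for the others. In deep CA1 all 10 groupings reached the real count of 0 calls, the highest other being 1, and the identifiers at an unadjusted p below 0.05 were 1947 against at most 1976, for the grouping of epileptic animal 1 with control animals 1 and 2. In superficial CA1 1 of 10 groupings reached the 2 calls, the highest other being 0, with 2710 identifiers against at most 1839 at an unadjusted p below 0.05.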

How the results depend on the processing

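The fold changes of the named identifiers and the share of control calls kept in epileptic rats held their direction under every alternative that was run. The balance of higher against lower calls did not. What caused the changes in count below was not tested. Fits with fewer animals gave more calls in some cases and fewer in others. Leaving out the 2 most abundant identifiers and the covariate were chosen after seeing the data. For the sublayer difference in controls (1248 calls), DESeq2 gave 820, limma-voom with quality weights 2523, limma-voom with the animal as a random effect 689, no low-count filter 1910, the 6 control libraries alone 2375, and a fit without the animal as a block 5. In epileptic rats (1484) the values were 820, 2585 and 838 for these tools, 727 for the 6 epileptic libraries alone and 5 without the block. For the difference between conditions of the sublayer effect (0), DESeq2 gave 2, limma-voom with quality weights 107 and no filter 178. In deep CA1 (0), RLE size factors gave 8, DESeq2 376, limma-voom with quality weights 2171, the random effect 47, no filter 103, 2 identifiers left out 8, the replicate block 239, all 12 libraries 48 and the covariate 99. In superficial CA1 (2), DESeq2 gave 885, limma-voom with quality weights 1789, the random effect 291, no filter 130, all 12 libraries 279, the covariate 5 and the replicate block 25. The number pairs different animals in both sublayers, and in superficial CA1 not every pair correlated. Leaving out 1 animal gave 416 to 2071 and 536 to 2217 calls for the sublayers in control and epileptic rats, 0 to 84 for their difference, and, leaving out 1 library, 0 to 552 in deep and 0 to 1443 in superficial CA1; those that moved a count by over 1.5 times are given with each comparison. The share of control calls with the same direction in epileptic rats was 92.15 to 97.36% without 1 epileptic animal, 94.98% with a wider choice of identifiers and 100% of 5 identifiers without the block. Over all alternatives the log2 fold change of the called superficial identifiers was 2.67 to 3.24 for ENSRNOG00000018159 and −3.60 to −2.85 for ENSRNOG00000054809, but both lost the call without any 1 control library, the former also without epileptic animal 2 (adjusted p = 0.06671) and with the covariate (0.08942). Among named identifiers, not counting the fits that left out 1 animal or library, 119 alternative values stayed on their side of the threshold, 55 newly passed and 9 no longer passed. The gene list tests and the alternative without mitochondrially encoded genes were not run. At 16135358 to 25893962 counts per library, low identifiers such as ENSRNOG00000045967, with 3 to 96 counts per library, rest on few reads.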

Other observations

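One hypothesis was that epilepsy differences are larger in superficial than in deep CA1. From the counts summed over both sublayers of each animal, 525 identifiers were chosen at an unadjusted p below 0.01, 201 risen and 324 fallen in epileptic rats (edgeR's quasi-likelihood test called 5 of 15398, with 2788 at an unadjusted p below 0.05). Their superficial minus deep log2 difference, signed by the direction of the epilepsy difference, was −0.03, 0.01 and 0.07 in epileptic animals 1, 2 and 3 and −0.09, −0.09 and −0.08 in control animals 1, 2 and 3. The group means differed by 0.10 (0.02 ± 0.05 against −0.09 ± 0.01, SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest that 3 animals against 3 can give). With identifiers chosen anew for each of the 9 other groupings of the 6 animals, a test chosen after the result was seen, the difference ranged from −0.11 to 0.16 on 2 to 254 identifiers. In total 2 of 10 groupings, the real one included, reached 0.101793, so a stronger response of superficial cells stays open. The difference is small beside the median absolute log2 fold change of 0.44 of these identifiers, and edgeR's quasi-likelihood test of single identifiers called 0, with 976 at an unadjusted p below 0.05, against 2 by DESeq2 and 107 by limma-voom with sample quality weights.

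A second hypothesis was that, in epileptic rats, identifiers higher in superficial cells in controls are lower relative to those higher in deep cells, averaged over both sublayers. The mean log2 CPM of the superficial-higher minus that of the deep-higher identifiers was 1.29, 1.16 and 0.77 in epileptic animals 1, 2 and 3 and 1.46, 1.38 and 1.28 in control animals 1, 2 and 3. The difference of the means was −0.3019, and epileptic animal 1 overlapped the controls (1.07 ± 0.27 against 1.38 ± 0.09, SD, n = 3 each; exact permutation test, two-sided, p = 0.2). Most of it came from the deep-higher identifiers, which were higher in epileptic rats by 0.23 (exact permutation p = 0.2), while the superficial-higher ones were lower by 0.07 without overlap of the animals (exact permutation p = 0.1) and the identifiers called in neither direction were higher by 0.06 (exact permutation p = 0.2). The data do not decide it at 3 animals per condition.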
